A study of Rattus norvegicus with 5 samples.

How the data were processed

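Total RNA from 4 rat hepatocellular carcinoma lines and 1 normal rat liver was hybridised to Rat Whole Genome CodeLink slides, 1 sample per slide. Per the file headers, the authors quantified the scans with CodeLink Expression Analysis. The deposited files give a raw intensity per spot, from which background is already subtracted, and a normalized intensity, which is the raw intensity divided by the median of the array. The deposited series matrix holds the same normalized intensity in every value (largest difference 0). Each array has 35129 spots, of which 33849 are discovery probes and 1280 are controls. Quality calls were G for spots above background and L for spots near background. Between 2274 and 2946 discovery probes per array were called irregular, 10 to 42 contaminated and 275 to 297 masked.

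The raw intensity was used. Control spots were left out, spots called irregular, contaminated or masked were set to missing, and signals were quantile normalised between the arrays with limma 3.58.1 in R 4.3.3. Signals were then floored at 2.53, the median normalised signal of spots near background, and taken to log2. Probes were kept when above background in liver or in at least 2 of the 4 lines, which left 16377. Tables were handled with data.table, version 1.17.8,, and statmod 1.5.0 served the robust alternative.

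Probe names came from the platform annotation, with symbols updated through Entrez gene numbers in a RefSeq gene table (assembly GRCr8), where 16836 of 16865 numbers matched. Of the discovery probes 16753 had 1 gene, 165 several and 16931 none, so that many probes count in the totals but cannot be named. Where a gene had several probes, the probe with the highest mean signal stood for it. No coordinates were used.

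One limma model with the groups liver, low-metastatic and high-metastatic was fitted to all 5 arrays, with empirical Bayes moderation (2 residual degrees of freedom at most, prior 1.46). The contrasts were high- minus low-metastatic lines, and the mean of both classes minus liver. All tests were two-sided and adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. The lone liver is assumed to vary as the lines do within their class. Probes whose usable spots left no residual degree of freedom were not tested, a choice made after the data were seen; 13741 and 11949 probes were tested. Because each line had 1 array, the error is the spread between lines of a class. No paired analysis was possible because the labels carry no shared replicate numbers, and no slide or scan term could be fitted because each slide held 1 array.

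A fold against a group whose spots were all near background is given as "at least", from the lowest signal called above background on the arrays of that group (14.6 in liver, 7.87 in C5F, 11.8 in C6, 13.0 in N1 and 11.2 in L2). A median "with bounds" sets such genes to their bound. Gene lists were tested with limma's camera on moderated z values, with a preset correlation of 0.01 and with an estimated correlation, which rests on 2 residual degrees of freedom, and adjusted over the 33 lists with at least 5 tested genes. The lists, 34 with 964 genes of which 811 were found, were written from textbook knowledge, and they, the tests and the rule for named genes were fixed before the data were examined.

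The rule named, for the classes, the 10 genes in each direction with the widest gap between the lowest array of the brighter and the highest array of the dimmer class, among genes above background on both arrays of the brighter class. For the lines against liver it named the 10 genes in each direction with the largest difference among those past the threshold. These genes had to change the same way in every line with a usable spot. It added up to 3 members per list with the largest difference, and always Alb, Afp, Gstp1, Gpc3, Cdh1, Vim, Cd44, Met, Spp1, S100a4, Mmp2, Mmp9, Nme1 and Mki67. Not every list member it named is described. Provisional names were left out.

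Classes were also compared without a test, by counting probes whose 2 arrays of a class lay at least 2-fold above both arrays of the other, beside the other 2 pairings of the lines. Arrays were compared by Pearson correlation across probes. The procedure was tested on simulated data with known differences in 40 runs for the classes and 20 for the lines against liver, with on average 1.48 and 1.30 false calls per run. Each run placed differences in 200 probes, all of them brighter ones, above a set mean signal in the lines. The NRF2 and glutathione list was called in 20 of 20 runs when shifted by 0.75, and with no shift in 0 of 20. This list is the only one called between the classes in the data, and the shift is near its median of 0.76 there. The simulated noise was independent between probes, so that false list calls from genes that vary together were not tested.

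Alternatives were scaling each array to the median of its probes above background or to its 75th percentile, an offset of 50, the deposited normalized intensity, no filter on dim probes, probes above background on all 5 arrays, a floor 2 times as high, irregular spots kept, a trended robust prior, the 4 line arrays only, a mean difference of 2-fold with no test, 3-fold separation, the estimated correlation, the mean of a gene's probes, and leaving out each line in turn. Keeping probes with no residual degree of freedom, and leaving out probes at the floor in all 4 lines, were alternatives chosen after seeing the data.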

Results

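RNA from 4 rat hepatocellular carcinoma cell lines and from 1 sample of normal rat liver was measured on 5 single-colour CodeLink whole-genome arrays. C5F and C6 are lines of low metastatic ability, and N1 and L2 are lines of high metastatic ability. The lines came from male F344 rats treated with N-nitrosomorpholine and diethylnitrosamine, and the labels give their age as 31 weeks. The reference was the liver of an untreated male SD rat of 50 weeks. Each line was measured on 1 array, so the 2 lines of a class are its replicates, and the liver has no replicate. Of 33849 discovery probes, the scanner software called 10367 (30.6%) above background in liver, 13276 (39.2%) in C5F, 11615 (34.3%) in C6, 11082 (32.7%) in N1 and 12185 (36.0%) in L2. The number of arrays limits the precision of every value below.

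The comparison of N1 and L2 with C5F and C6 asks which transcripts go with metastatic ability. The NRF2 and glutathione list holds genes that defend cells against oxidants and electrophiles, and also Nfe2l2, the gene of NRF2, and its inhibitor Keap1. Genes of this list were higher in the high-metastatic lines. The median log2 difference was 0.76 over 17 tested genes (camera adjusted p = 4.77e-06, and adjusted p = 4.92e-07 with an estimated correlation). The estimated correlation of this list was 0, below the preset 0.01, so that the second p-value is the more lenient. The median was 0.45 with an offset of 50 added to the signal. Of 19 members with a value, 17 were higher on average in N1 and L2. Of the 14 members measured in all 4 lines, 11 had both of these lines above both low-metastatic lines, against 0 the other way round. Chance separates the classes in either direction for 33.3% of such genes. The 14 members were read on the same 4 lines and may vary together, so they are not independent trials against that share. Nqo1, a quinone reductase, differed by 1.75 ± 0.35 on the log2 scale (SE, n = 2 lines per class). Slc7a11, the cystine importer that feeds glutathione synthesis, differed by 1.58 ± 0.58, and Me1, an enzyme that supplies NADPH, by 1.14 ± 0.51. Among members chosen after their values were seen, the pentose phosphate enzymes Tkt and Taldo1 differed by 1.14 ± 0.23 and 0.76 ± 0.20, and thioredoxin reductase Txnrd1 by 0.76 ± 0.24. Keap1, also chosen afterwards and counted among the 17 and the 11, differed by 0.84 ± 0.43. Nfe2l2 differed by 0.24 ± 0.26, without a usable spot in N1. Hmox1, the inducible haem oxygenase, and Ephx1, an epoxide hydrolase, pointed the other way, with −0.54 ± 0.93 and −0.47, the latter from 1 line per class. For Ephx1 the only usable high-metastatic spot, in L2, was near background, so that −0.47 is a fitted value and no measured size. Leaving out each line in turn gave 0.97 to 2.23 for Slc7a11 and 0.52 to 1.74 for Me1, and Hmox1 turned to 0.44 without L2 and to 0.16 without C5F. None of the 17 genes passed the limma test singly, and 0 passed adjusted over the list alone.

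**Figure D1:**
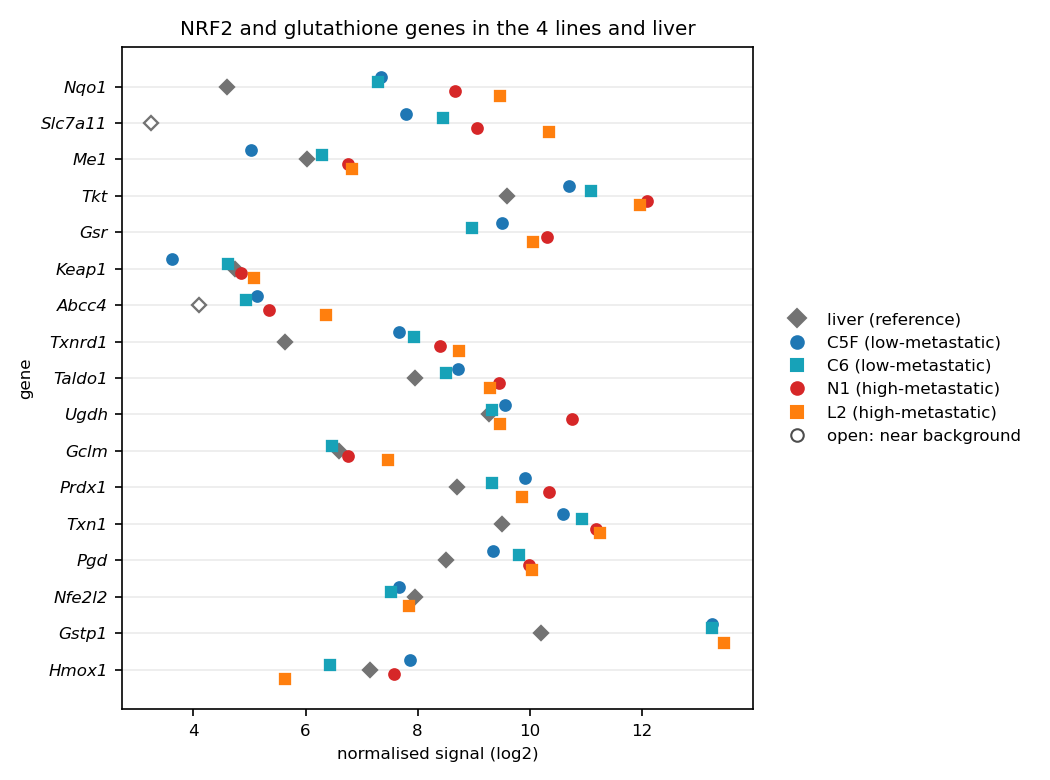
Normalised log2 signal (horizontal axis) of the 17 tested genes of the NRF2 and glutathione list (vertical axis, ordered by the difference between the classes), with 1 point per array and open points for spots near background. For Nqo1 the high-metastatic lines lie at 8.68 and 9.48 and the low-metastatic lines at 7.35 and 7.30.

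Single genes set the classes further apart, although 0 of 13741 tested probes passed limma's adjusted p (lowest 0.489), with 1005 probes (7.31%) at an unadjusted p under 0.05. Aldh3a1, an aldehyde dehydrogenase often raised in hepatocarcinoma, stood at 10.1 and 10.2 in N1 and L2 and at 5.97 in C6, and was near background in C5F, a difference of 6.32 ± 1.64. Glrx, a glutathione-dependent reductase of protein disulfides, was at least 34.3-fold brighter in the high-metastatic lines, being near background in C5F and C6. Tceal9, a protein of the transcription elongation factor family, differed by 4.35 ± 0.34, and Ptprn, a phosphatase-like protein of secretory granules, by 3.29 ± 0.29. Zfp775, a zinc finger protein, differed by 3.36 ± 0.32, with C6 near background. Sparc, a matricellular glycoprotein, differed by 4.64 ± 0.997 on its brighter probe, with C6 near background, and by 1.16 on the other. Lgals3bp, a galectin-binding glycoprotein, was 7.97-fold brighter, but its second probe gave a log2 difference of −0.20. Sftpc, a surfactant protein of lung, the homeobox gene Hoxd8 and the transporter Abcg3l1 were near background in both low-metastatic lines and at least 17.2-fold, 1.79-fold and 1.57-fold brighter in N1 and L2.

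The 10 genes with the widest gap in the other direction were all near background in both N1 and L2. Igfbp1, a hepatic binding protein of insulin-like growth factors, was at least 18.4-fold dimmer in the high-metastatic lines, and its log2 signal was 10.9 in C5F and 4.71 in C6. The water channel Aqp8 was at least 14.7-fold dimmer, the kinesin Kif12 at least 6.27-fold, the secreted stanniocalcin Stc2 at least 4.25-fold and the putative retinol transporter Stra6l at least 4.20-fold. Cyp26a1, which breaks down retinoic acid, was at least 2.59-fold dimmer, and Dph2 at least 2.15-fold. For Asb13, Hdac11 and Alox12 the bounds were 1.55-fold, 1.49-fold and 1.39-fold. The 20 genes of the widest gaps had adjusted p-values from 0.489 to 0.682.

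**Figure D2:**
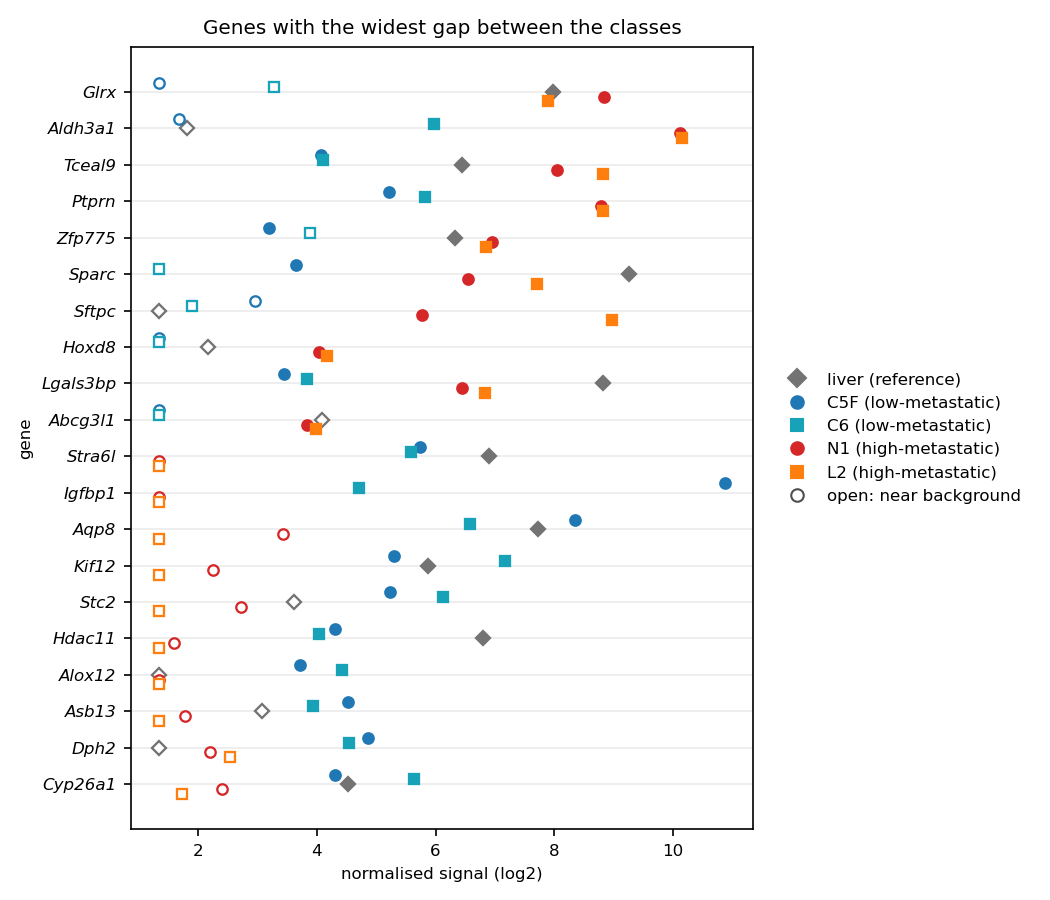
Normalised log2 signal (horizontal axis) of the 10 genes with the widest gap towards the high-metastatic lines and the 10 with the widest gap towards the low-metastatic lines (vertical axis), with 1 point per array and open points for spots near background. Tceal9 lies at 8.05 and 8.83 in the high-metastatic lines, at 4.06 and 4.11 in the low-metastatic lines and at 6.44 in liver.

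Of the 33 lists tested, the NRF2 list was the only one called between the classes, and the other 32 had adjusted p-values from 0.216 to 0.901. In the mesenchymal transition list, 13 of 17 genes pointed higher in N1 and L2 (median 0.68, or 0.42 with genes near background at their bound; adjusted p = 0.216). Its member Vim, the intermediate filament of mesenchymal cells, differed by 2.00 ± 1.14 (0.63 to 3.39 without each line in turn). Cdh2, N-cadherin, with a usable spot in only 1 low-metastatic line, differed by 1.97 ± 2.25, which became −0.055 without L2. S100a4, a calcium-binding protein linked to motility, differed by 1.52 ± 1.01 (0.57 to 2.55 without each line). The epithelial cadherin Cdh1 differed by −3.15 ± 1.86, being near background in L2 alone (second probe −1.36, and −5.47 to −0.83 without each line), and the gap junction gene Gja1 was at least 3.92-fold brighter in N1 and L2. Among adhesion receptors Alcam differed by 2.61 ± 0.59 and Icam1 by −3.01 ± 0.26 (second probe −0.17), each with a usable spot in only 1 high-metastatic line. Of matrix proteases, Mmp11 differed by 1.99 ± 0.41 without a usable spot in L2. Mmp14 was above background in L2 alone among the lines. Its class difference was −0.33 to 5.37 without each line in turn, the lowest without L2. Of cytoskeletal genes, Tmsb4x, which binds actin monomers, differed by 4.85 ± 2.42 with C5F near background (2.19 to 7.45 without each line), and Vil1, villin of the brush border, was at least 9.34-fold dimmer in L2, with no usable spot in N1. Car9, a carbonic anhydrase induced by hypoxia, differed by 4.01 ± 0.30 without a usable spot in L2, and was the 1 gene of all lists to pass adjusted over the list alone. The bile acid enzyme Cyp27a1 was at least 16.8-fold dimmer in L2, the only high-metastatic line with a usable spot.

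Several liver genes differed between the classes through C5F alone. Afp, the fetal serum protein reactivated in hepatocarcinoma, had a log2 signal of 11.8 in C5F and 7.68 in liver, but 4.47 in L2 and near background in C6 and N1. Its class difference of −3.97 ± 3.92 became 0.99 without C5F. Gpc3, an oncofetal proteoglycan, stood at 10.2 in C5F and at most 4.43 in the other lines, so that −2.91 ± 2.31 became 0.12 without C5F, and its second probe gave 0.73. The plasma proteins Tf, Ttr and Serpina1 were above background in C5F only among the lines. Their fitted class differences of −3.78, −3.68 and −3.61 average C5F with C6, which was near background, so they are no bounds. Leaving out each line in turn gave −7.51 to 0 for Tf, −7.32 to 0 for Ttr and −7.13 to −0.057 for Serpina1. Alb was near background in all 4 lines. The metastasis and tumour genes Cd44 (−0.86 ± 0.93, and −1.70 to −0.052 without each line in turn), Met (−1.23 ± 1.01, and 0.066 without N1), Nme1 (−0.32 ± 0.23, and −0.51 to −0.12 without each line), Mki67 (−0.27 ± 0.25) and Gstp1 (0.22 ± 0.25) differed by less than 1.5 times their errors, with no usable spot for Cd44 in C5F, Mki67 in C6 and Gstp1 in N1. Mmp2 had 1 usable spot per class and no test, and Spp1 and Mmp9 did not pass the filter on dim probes.

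Over all probes the class division was weak. Among 9352 probes measured in all 4 lines, 134 were at least 2-fold higher in both high-metastatic lines and 103 in both low-metastatic lines, 237 in all. Pairing C5F with N1 against C6 with L2 gave 218 such probes, and pairing C5F with L2 gave 115. The classes did not overlap for 36.7% of probes, where chance gives 33.3%. With C5F paired with N1 the share was 32.2%, and with C5F paired with L2 it was 27.1%. Probes at an unadjusted limma p under 0.05 numbered 1005 for the classes, and 725 and 445 for these pairings. Across tested probes, which are not independent replicates, the log2 signals of C5F and C6 correlated with r = 0.907 and those of N1 and L2 with r = 0.886, while pairs from different classes had r between 0.852 and 0.906. With 2 lines per class the test sees only very large effects. On simulated data for this comparison it recovered 0% of 2-fold, 0.112% of 4-fold and 39.0% of 16-fold differences. These were placed in brighter probes only, 200 per run among 13741 probes tested. The list count of 1 was 2 when each array was scaled to the median of its probes above background and 4 when irregular spots were kept. In 7 lists not called here (liver transcription factors, glycolysis, metastasis suppressors, cytoskeleton, fatty acid and sterol synthesis, cholangiocyte markers, ribosomal proteins) the median, mean and test differed in sign.

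The comparison of the 4 lines with liver, the reference of the series, asks what sets the carcinoma lines apart from the tissue. Genes of the hepatocyte were lower in the lines and genes of cell division higher: 1077 probes were higher and 1121 lower than in liver among 11949 tested (limma adjusted p from 0.00627). Alb, the main plasma protein of hepatocytes, fell at least 263-fold. Cyp2e1, an ethanol-metabolising cytochrome, fell at least 430-fold, without a usable spot in C5F. Ccne1, the cyclin of entry into S phase, rose at least 7.90-fold, and Pkm, the pyruvate kinase of growing cells, rose by 4.70 ± 0.29 on the log2 scale (SE, n = 4 lines against 1 liver). Dimmer probes of these genes gave fitted log2 differences of −8.64 for Cyp2e1 and 2.88 for Ccne1, and the lowest of the 3 Pkm probes gave 2.74; fitted values of second probes are no bounds and can depend on the floor. The call rests on the lone liver varying as the lines do within a class, and strain, age and culture differ along with tumour. The list tests against liver take genes as their units, and all genes share the same liver array. Their p-values therefore do not measure the spread between livers. The counts were 0 higher and 0 lower without C5F and also without C6, 114 and 476 without N1, and 132 and 485 without L2.

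Plasma proteins and clotting factors fell together. Of 18 tested genes of complement and coagulation, 16 fell and 17 adjusted over the list alone (median −5.10, or −4.29 with bounds; camera adjusted p = 1.85e-11), among them the clotting factors F10 (at least 171-fold, with −7.24 on the log2 scale from its second probe) and F12 (at least 129-fold). Of 14 hepatocyte secreted proteins 8 fell, 9 adjusted over the list alone (median −9.10, or −8.10 with bounds; adjusted p = 1.88e-07). Ahsg, fetuin-A, fell by 10.42 ± 1.40, a size set largely by the floor, since only C5F among the lines was above background. Ambp, the precursor of bikunin, fell at least 815-fold, without a usable spot in C5F, and Mug1, a proteinase inhibitor, at least 191-fold. In the acute phase list 2 of 12 genes fell, with 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.0319): the chemokine Ccl5 and Crp, C-reactive protein, the latter at least 211-fold. That list lost its call without N1 (adjusted p = 0.223).

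Lists of hepatic metabolism were lower too, some with few genes called or with a call that depended on the settings. Of 21 genes of cytochrome P450 and conjugation 16 fell, 18 adjusted over the list alone (median −5.95, or −5.05 with bounds; adjusted p = 1.97e-11). Cyp2d2 fell at least 441-fold and Cyp2c12 at least 248-fold; the latter is known as female-predominant but was bright in this male liver, its second probe gave −6.14 on the log2 scale, and whether these probes also detect close relatives was not tested. The glutathione transferase Gstp3 fell at least 218-fold. Of 10 genes of bile acid synthesis and transport 8 fell, 10 adjusted over the list alone (adjusted p = 2.16e-07, and adjusted p = 0.0277 with an estimated correlation). Slc27a5, the bile acid ligase, fell at least 426-fold, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at least 38.5-fold and the uptake transporter Slco1b2 at least 52.3-fold. Of 11 genes of the urea cycle and amino acid breakdown 9 fell, 10 adjusted over the list alone (adjusted p = 5.21e-07, but adjusted p = 0.0519 with an estimated correlation), with Cps1, the entry enzyme of the urea cycle, at least 46.8-fold and Tdo2, which degrades tryptophan, at least 151-fold. Of 8 genes of gluconeogenesis 6 fell, 7 adjusted over the list alone (adjusted p = 2.60e-06, and adjusted p = 0.0106 with an estimated correlation). Pck1 fell at least 94.4-fold and G6pc1 at least 68.0-fold. Of 13 genes of fatty acid oxidation 7 fell, 8 adjusted over the list alone (adjusted p = 0.000122, but adjusted p = 0.185 with an estimated correlation), with the fatty acid binding protein Fabp1 by 8.05 ± 1.36, a size set largely by the floor since only N1 among the lines was above background, and the ketone body enzyme Bdh1 at least 29.6-fold. In fatty acid and sterol synthesis 1 of 17 genes fell, and 1 adjusted over the list alone: the desaturase Fads2, by 3.30 ± 0.32 (adjusted p of the list 0.0319, from 0.0503 to 0.233 without each line in turn). Thrsp, a lipogenic gene outside that list, fell at least 245-fold. Of 6 liver transcription factors 2 fell, 3 adjusted over the list alone (adjusted p of the list 0.0602): Hnf4a by 2.07 ± 0.30 (the largest of its 3 probes −4.36) and Foxa1 at least 6.15-fold.

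**Figure D3:**
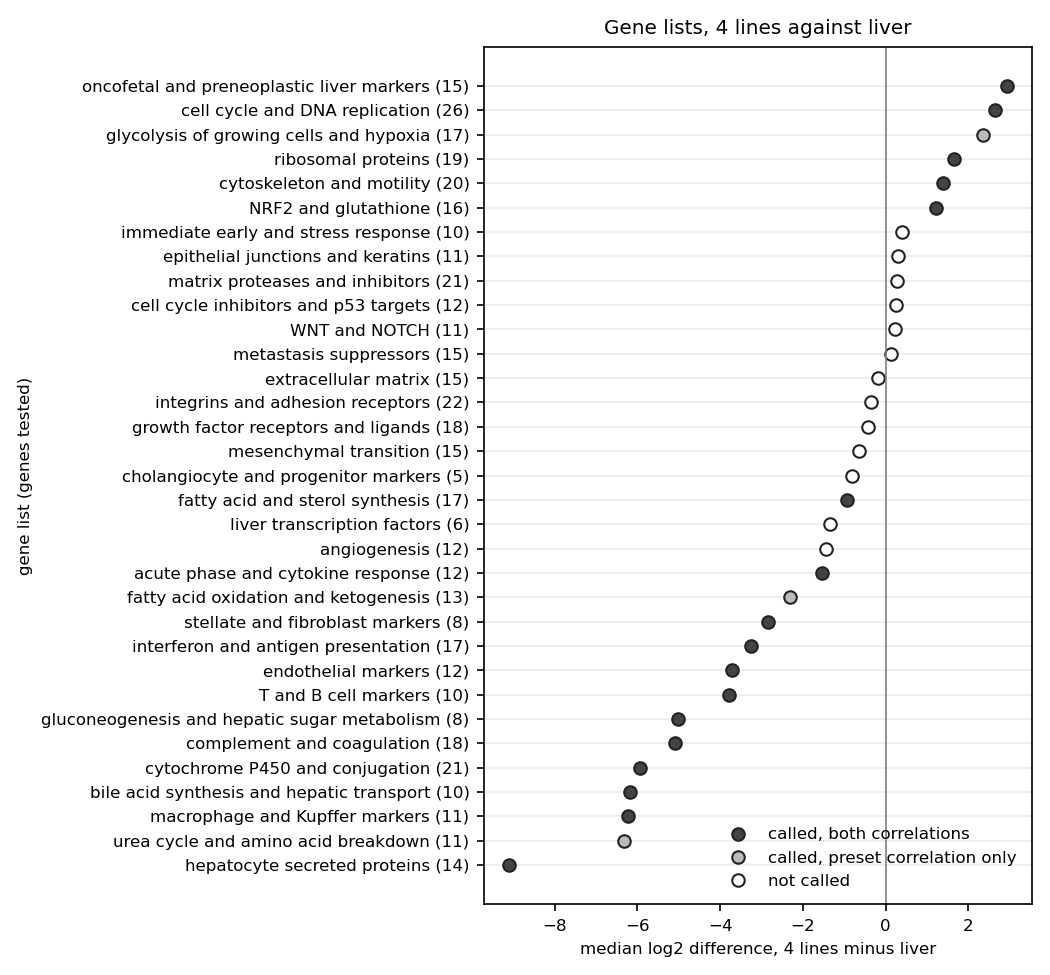
Median log2 difference between the 4 lines and liver (horizontal axis) of the 33 tested gene lists (vertical axis, genes tested in brackets), filled where the list was called with both correlations, grey where with the preset correlation only and open where not called. The hepatocyte secreted proteins lie lowest at −9.10, and cell cycle and DNA replication lies at 2.64; these medians use fitted values for genes near background.

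Cell division genes rose together: 22 of 26 tested genes of cell cycle and DNA replication rose, 23 adjusted over the list alone (median 2.64, or 2.54 with bounds; camera adjusted p = 8.89e-10). Rrm2, the ribonucleotide reductase subunit of S phase, rose at least 5.71-fold, Ccna2, cyclin A2, at least 16.4-fold and Mki67, the proliferation antigen, at least 6.40-fold. The inhibitors of cyclin-dependent kinases Cdkn2a and Cdkn2b rose at least 11.3-fold and 22.3-fold, the 2 genes to rise among 12 of cell cycle inhibitors and p53 targets (4 adjusted over the list alone; adjusted p of the list 0.399). In the glycolysis and hypoxia list 8 of 17 genes rose, 9 adjusted over the list alone (median 2.35, or 2.33 with bounds; adjusted p = 5.28e-05, but adjusted p = 0.0927 with an estimated correlation), with Pkm and the glucose transporter Slc2a1, by 4.04 ± 0.23. Of 19 ribosomal protein genes 10 rose, 17 adjusted over the list alone (median 1.66, or 1.63 with bounds). The list had adjusted p = 3.50e-06, and adjusted p = 0.0392 with an estimated correlation. Rpl6 rose by 2.31 ± 0.31, while its second probe gave 0.07, and Rpl28 rose at least 1.37-fold. In cytoskeleton and motility 4 of 20 genes rose, 8 adjusted over the list alone (median 1.39, or 1.06 with bounds; adjusted p = 0.00754), namely the actin regulators Cfl1, Actr2 and Vasp and the tubulin regulator Stmn1, of which Vasp rose by 2.86 ± 0.20 (second probe 2.37).

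In the NRF2 and glutathione list 6 of 16 genes rose, 8 adjusted over the list alone (median 1.22, adjusted p = 0.00603). Slc7a11 rose at least 32.9-fold (its second probe gave a log2 difference of 2.05) and Nqo1 by 3.59 ± 0.39. Gstp1, the placental transferase that marks preneoplastic rat liver, rose by 3.17 ± 0.24, without a usable spot in N1. Among oncofetal and preneoplastic markers 5 of 15 genes rose (Abcc1, Anxa2, Akr1b8, Gpx2, Gstp1) and 1 fell (Akr1b10), with the same counts adjusted over the list alone (median 2.94, or 0.83 with bounds; adjusted p = 0.0380). That call was lost without C5F (adjusted p = 0.123), with the mean of a gene's probes (0.0710), with irregular spots kept (0.0515) and among probes above background on all 5 arrays (0.148). Akr1b8, an aldo-keto reductase, rose at least 45.0-fold and Gpx2, an epithelial glutathione peroxidase, by 5.37 ± 0.51. Afp (−2.79 ± 4.38, and −5.26 to −0.29 without each line in turn) and Gpc3 (0.41 ± 2.59, −1.07 without C5F, and −2.83 on its second probe) did not pass. Outside the lists, Igf2bp2, a fetal RNA-binding protein, rose at least 20.8-fold and the AMP deaminase Ampd3 at least 15.8-fold (second probe 1.49 on the log2 scale). The annotated pseudogene Nid2-ps16 rose at least 8.64-fold, the amine oxidase Aoc3 at least 8.24-fold and the tetraspanin Tspan17 at least 8.01-fold. Clic1, a chloride channel protein, rose at least 6.94-fold. Ampd3, Aoc3 and Tspan17 had no usable spot in C5F, Nid2-ps16 none in L2 and Clic1 none in C6.

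Markers of the other cells of liver tissue fell too. Of 11 macrophage and Kupffer cell markers 9 fell, 10 adjusted over the list alone (median −6.22, or −5.39 with bounds; camera adjusted p = 6.12e-08), with Tyrobp at least 112-fold and C1qa at least 49.8-fold. Of 10 T and B cell markers 6 fell, 10 adjusted over the list alone (median −3.77, or −1.98 with bounds; adjusted p = 1.97e-06), with Prf1, perforin, at least 63.5-fold. The interferon and antigen presentation list is a pathway list and not one of cell type markers. In that list 6 of 17 genes fell, 10 adjusted over the list alone (median −3.25, or −3.07 with bounds). Its camera adjusted p was 5.14e-06, and Cd74, the invariant chain of class II molecules, fell at least 66.4-fold. Of 8 stellate cell and fibroblast markers 7 fell, 7 adjusted over the list alone (adjusted p = 1.22e-05), with decorin, Dcn, at least 4.40-fold. Of 12 endothelial markers 5 fell, 5 adjusted over the list alone (adjusted p = 0.00258), namely Tek, Kdr, Stab1, Stab2 and Lyve1 of sinusoidal endothelium, the last at least 19.9-fold. Only 3 erythroid markers could be tested, too few for a list test. Alas2 fell at least 9.93-fold, Car1, with usable spots in only 3 lines, fell by 1.89 ± 0.25 and Tfrc, the transferrin receptor, rose by 2.74 ± 0.28.

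Lists of invasion and cell identity were not called against liver. In matrix proteases Mmp11 and Plaur rose and Ctss, Mmp15 and Plau fell, 2 and 3 of 21 genes (adjusted p = 0.880), and Plaur, the urokinase receptor, rose at least 12.1-fold. In metastasis suppressors 2 of 15 genes rose, Nme2 and Rrm1, and 2 fell, among them Rarres2 (adjusted p = 0.972). In extracellular matrix P4ha1 and Lamb2 rose and Lox, Lama4, Col6a1, Dcn and Col18a1 fell, 2 and 5 of 15 genes (adjusted p = 0.449). In growth factor receptors Erbb2 rose and Egfr, Pdgfrb, Kdr and Fgfr4 fell, 1 and 4 of 18 genes (adjusted p = 0.100), and in WNT and NOTCH Myc, Fzd6 and Jag2 rose, 3 of 11 genes (adjusted p = 0.458). In integrins and adhesion receptors 6 of 22 genes fell (adjusted p = 0.257), and in angiogenesis 3 of 12, among them Tek and Col18a1 (adjusted p = 0.0641). In mesenchymal transition Zeb2 and Thy1 fell, 2 of 15 genes (adjusted p = 0.215), in cholangiocyte markers Tm4sf4 and Prom1, 2 of 5 (adjusted p = 0.316), and in immediate early genes Herpud1, 1 of 10 (adjusted p = 0.884). In epithelial junctions 0 of 11 passed (adjusted p = 0.880), with Cdh1 at −2.81 ± 2.07, near background in L2 alone (−3.97 to −1.69 without each line in turn). Genes named against liver with no value of their own were chosen after their values were seen. Counts adjusted over the list alone in these 11 lists were from 0 to 4 higher and from 0 to 7 lower. S100a4 (4.63 ± 1.13, adjusted p = 0.0762), Cd44 (at least 7.83-fold brighter, adjusted p = 0.114) and Met (−1.36 ± 1.12, and −2.00 to −0.70 without each line) did not pass, Mmp2 (−1.18, and 0.24 on its second probe) had too few spots for a test, and Vim and Nme1 had no usable liver spot. Of the 63 genes given with values against liver 56 passed. Car1, Rpl6, Cdkn2a and Hnf4a lost the call when each array was scaled to the median of its probes above background, Car1 and Rpl6 also at the 75th percentile, and Car1, Gstp1 and Rpl6 with the deposited normalised values. On simulated data for this comparison the test recovered 0% of 2-fold, 0.299% of 4-fold and 33.2% of 16-fold differences. These were placed in brighter probes only, 200 per run among 11949 probes tested. In the data 2198 probes were called. More true differences make the adjusted threshold more lenient, so these shares can understate the recovery in the data. For epithelial junctions, matrix proteases and metastasis suppressors the median, mean and test differed in sign.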

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

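Leaving out each line was decided on beforehand, but its use as a test of whether a single line carries the pattern was chosen after its result was seen.

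The NRF2 and glutathione list stood out because its genes differed between the high- and low-metastatic lines (adjusted p = 4.77e-06). A bias of the arrays that depends on brightness is argued against, since the median of 0.76 lay at percentile 100 of 10000 random lists matched on mean signal, whose middle 95% ran from −0.25 to 0.26. A single line as the cause is argued against by an adjusted p of at most 0.00145 without each line in turn, where the class left with 1 array is assumed to vary as the other class does. A difference between lines that has nothing to do with class stays open, since the 4 lines have only 3 pairings, too few for a share under 0.05: the list's mean z was 1.49 for the classes and at most 0.0681 for the other pairings, yet the pairing of C5F with N1 called 3 other lists. Metastatic ability itself may go with the list, but with 2 lines per class it cannot be told apart from other ways in which these lines differ.

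Tceal9 and Zfp775 stood out because both high-metastatic lines lay above liver and both low-metastatic lines below it, with class differences of 4.35 and 3.36. Zfp775 was near background in C6. That the classes depart from liver in opposite directions was not tested, and the class difference did not pass (adjusted p = 0.602 for each).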

How the results depend on the processing

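Between the classes 0 probes passed under any alternative tested with limma, with unadjusted p under 0.05 for 235 to 2456 probes and a lowest adjusted p of 0.0593. A mean difference of 2-fold with no test gave 930 higher and 848 lower. The NRF2 list kept its call under its 15 alternatives (median from 0.45 to 0.82, adjusted p at most 0.00132). The deposited values count among these both as the series matrix and as the normalized intensity, which are the same. The number of lists higher in the high-metastatic lines was 2 with scaling to the median of its probes above background and 4 with irregular spots kept, and 1 to 2 without each line in turn, with 0 to 1 lower; the cause was not tested. Probes 2-fold higher in both high- and both low-metastatic lines numbered 52 and 31 at 3-fold separation, 298 and 260 without the filter, 14 and 6 with the offset of 50, which shrinks dim differences, and 17 and 6 among probes above background on all 5 arrays, where fewer were compared. The correlation of the high-metastatic lines was 0.914 without the filter, 0.926 with the offset and 0.943 for probes above background on all arrays. That of the low-metastatic lines was 0.941 and 0.955 in the latter cases, and the mean between classes 0.913, 0.924 and 0.943.

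Against liver the counts higher and lower were 623 and 1725 without the filter, 320 and 255 for probes above background on all 5 arrays, where 3338 were tested and 2 lists were lower, and 0 to 132 and 0 to 485 without each line in turn, with fewer residual degrees of freedom. The count higher was 473 with the offset of 50 and 1804 with irregular spots kept; the causes were not tested. Lists numbered 5 to 6 higher and 13 to 15 lower without each line. Scaling to the median of its probes above background moved the median of all probes from 0.16 to 0.31 against liver and to −0.13 between the classes, and the 75th percentile to 0.24 against liver. Over alternatives other than leaving out lines, gene values against liver stayed on their side of the threshold in 649 cases, lost it in 48 (19 without the filter, 10 with the offset) and gained it in 1, and list values did in 261 and lost it in 6, of which 3 with the estimated correlation. The deposited values were counted in both forms among these cases too. Genes not past the threshold reversed between the classes as follows. Mki67 gave 0.0087 with the deposited values. Without each line in turn the ranges were −8.88 to 0.99 for Afp, −0.055 to 3.97 for Cdh2, −5.91 to 0.12 for Gpc3 (−1.07 to 1.91 against liver), −1.47 to 0.44 for Hmox1, −2.50 to 0.066 for Met and −0.33 to 5.37 for Mmp14, where Hmox1 reversed without L2 and without C5F. A block for slide or scan was not run, since each slide held 1 array. Signal over background limits the folds of genes near background to bounds.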

Other observations

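The tests in this part were all chosen after their results were seen, as was the rule that a gene marks a line when it lies 8-fold above or below each of the other 3 lines, applied to 4447 genes with 4 values.

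C5F had 22 such genes higher and 17 lower, L2 12 and 13, N1 10 and 2, and C6 5 and 2. In C5F the lipid carrier Apoe had a log2 signal of 10.4 and was near background in the other lines, H19, an imprinted fetal RNA, stood at 9.89 against at most 5.04, and the lipocalin Apom at 8.66 against at most 4.27. The annexin Anxa1 was lower in C5F, 6.98 against at least 10.2, as was the caveolar protein Cavin3, 4.91 against at least 8.46. L2 had the epithelial cadherin Cdh1, the polarity gene Crb3 and the intestinal lectin Lgals4 near background, where the other lines had 9.41 to 10.9 for Lgals4. Its signal of Timp1, an inhibitor of matrix proteases, was near background against 7.09 to 8.21 in the others, while the membrane protease Mmp14 stood at 7.05 and carboxypeptidase E, Cpe, at 8.76. N1 alone had high Plac8 (11.1) and the macrophage gene Mpeg1 (6.84). These are values of single arrays.

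Liver RNA in the C5F sample may be proposed for its Afp, Tf, Ttr and Serpina1. Taking Tf, Ttr, Serpina1 and F2, it would need a share of 9.32% (4.55% by the lowest of the 4), but of 37 genes bright in liver and near background in the other lines 27 (73.0%) were near background in C5F too, where that share predicts signal a median of 5.38 log2 higher. Alb would need 8.05 and measured 1.34, and Afp, at 11.8, lay above its 7.68 in liver. These values argue against liver RNA as the cause. No biological explanation was tested.

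The lower macrophage, T and B cell markers in the lines may come from other cell types in the liver tissue. Of 21 markers above background in liver, 16 (76.2%) were near background in every measured line, and 1 is in another list; Tyrobp, for example, had a log2 signal of 10.2 in liver. Since these markers were already called lower, this share decides nothing, and the explanation stays open. For endothelial, stellate and fibroblast markers 9 of 22 (40.9%) were, 8 of the 22 are in another list, and carcinoma cells may express them, so that for both groups loss from tumour cells and absence of other cells cannot be told apart. Strain, age and culture stay open as untested differences.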
